A study of Mus musculus with 4 samples.

How the data were processed

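Messenger RNA was sequenced from tumour-associated macrophages of 4 mouse samples, 2 labelled control and 2 labelled OXCT1mKO, the genotype in which Oxct1 is named as the targeted gene. Per the labels' protocols, liver tissue was minced and digested with collagenase IV, leukocytes were enriched on a Percoll density gradient, and macrophages were isolated by flow sorting. The antibodies of the sort are not given in the sources used here. The same protocol text names an oligonucleotide microarray, whereas the series type is sequencing and the values are RPKM, so the text does not describe the measurement used here. Each sample was assigned to its group and replicate number from its own title, and the genotype label of each sample gave the same group.

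The authors deposited 1 table of RPKM values (reads per kilobase of gene model, scaled to the size of the library), with 1 row per gene symbol and 1 column per sample. Per the submitters' processing notes, STAR 2.10 and R 4.0.5 were used and the genome build was mm10, with no role or order stated for either tool. The read counter, its strand setting, the annotation, the gene lengths and the definition of the library size are not given in the sources used here. The table held 24784 genes, of which 19514 had a value above 0 in at least 1 library. Of the genes above 0, 113 had values identical to those of another row, in 49 groups, as for gene copies that share reads. The table held 0 genes encoded in mitochondrial DNA.

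RPKM values are not counts, so no count model was fitted. The absolute depth is unknown, because the values of low genes did not resolve into whole reads. Ratios of the values of genes with a mean RPKM up to 0.05 peaked at 1 value for each pair of libraries, counted within a tolerance of 0.1%. These peaks placed the relative depths at 1.026 for control 2, 0.966 for OXCT1mKO 1 and 0.91 for OXCT1mKO 2, with control 1 set to 1. No interval or detection limit that needs a read count is given.

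Values were transformed to log2(RPKM + 1), and 12523 genes with a mean RPKM of at least 1 over the 4 libraries were tested. A linear model with 1 coefficient for the group was fitted in limma 3.58.1 under R 4.3.3, with moderated variances that follow a trend in mean level. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes, and are given with their standard errors (SE). An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, which is why a model that shares the spread over genes was used. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

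Before the data were examined, 45 gene lists were fixed, 28 of processes and 17 of cell types, together with the test designs and the rule for the genes named in the text. The named genes were Oxct1, the 10 genes with the largest fold change in each direction among changed genes whose libraries separated by group, up to 4 members with the smallest p in each list, and a fixed set of 10 macrophage, liver and neutrophil genes. That set was Arg1, Mrc1, Cd274, Nos2, Cd86, Lyz2, Adgre1, Csf1r, Alb and S100a8. Predicted and clone-named genes were left out of the ranking by fold change. Other list members are named where few members of a list moved one way, and those were chosen after their values were seen, as were Malat1 and Ptprc. Some genes that the rule selects are not reported here. Lists with at least 5 tested members were tested with limma's camera on the same fit, with the correlation between genes preset to 0.01 and Benjamini-Hochberg adjustment over 43 lists. Camera with a correlation estimated for each list was run beside it. That version has only the 2 residual degrees of freedom of the fit, which leaves it little power. A call that it does not make is therefore not shown to be undone by correlation between genes. Fry was run too. It asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Within each list, p-values were also adjusted over the list alone.

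Summed exon lengths, GC contents and gene positions came from the GENCODE mouse annotation and genome of build GRCm38, release M21, the assembly also called mm10. A length was found for 97.6% of symbols. For the comparison of fold change with length, 12310 tested genes had both length and GC content.

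The fit and the list test were run on simulated data for the 12523 genes, 200 of them changed, in 10 runs. Each gene kept its mean, and its errors were drawn independently of other genes with a spread scaled from its own. Genes that move together were not simulated, so the rates do not carry over to lists or to differences shared by whole libraries. Only 200 genes were changed, whereas 4110 passed in the data, so the adjustment was stricter in the simulation. The shares recovered therefore do not give the power of the real comparison. The share of changed genes recovered was 17.4% at a log2 change of 0.5, 77.8% at 1, 93.4% at 2 and 99% at 4, with a mean of 8.2 false calls per run. Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter and a minimum mean of 5 RPKM, median-of-ratios and quantile scaling, moderation without a trend and with a robust fit, the replicate number as a block, each library left out in turn, removal of predicted genes and pseudogenes, other thresholds, and other list tests. A correction of each library for gene length and GC content with splines of 5 degrees of freedom was added after the data were examined. So were a variance per group, a scaling that leaves globin genes out of the sum, and camera with an estimated correlation after the length and GC correction. That scaling set the RPKM sums of the libraries equal without globin genes, whereas the main fit used the deposited values unscaled. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.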

Results

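Polyadenylated RNA was profiled in tumour-associated macrophages sorted from liver tumours of male mice aged 6 to 8 weeks that had been given Hepa 1-6 cells, a mouse hepatoma line. There were 2 libraries labelled control and 2 labelled OXCT1mKO, a genotype label that names Oxct1 as the target. This gene encodes the mitochondrial enzyme that activates acetoacetate for use as a fuel in ketone body breakdown. The deposited RPKM values summed to 377575 and 355951 in control 1 and control 2 and to 327811 and 325034 in OXCT1mKO 1 and OXCT1mKO 2. The read depth is unknown, but ratios between low values placed the relative depths of the libraries between 0.91 and 1.026. On the log2(RPKM + 1) scale, the Pearson correlation across genes was 0.976 between the controls, 0.988 between the OXCT1mKO libraries and 0.922 to 0.947 between groups. Globin transcripts made up 6.46% of the RPKM sum in control 1, against 0.237% in control 2 and 0.1% and 0.095% in the OXCT1mKO libraries.

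The first question was whether the transcript named in the label was lower in the samples labelled OXCT1mKO. Oxct1 lies on chromosome 15 of build GRCm38, from 4026383 to 4155344 on the plus strand. Its level was 19.3 and 20.3 RPKM in the controls and 14.7 and 15.4 RPKM in the OXCT1mKO libraries, a mean of 19.8 ± 0.68 against 15.1 ± 0.48 RPKM (SD, n = 2). The log2 fold change was -0.37 ± 0.09 (SE), with a limma adjusted p of 0.0346. Of all tested genes 32.8% passed that threshold, and the oxidative phosphorylation and TCA cycle lists had medians of -0.45 and -0.27. The Oxct1 fall therefore cannot be told from a shared fall of mitochondrial genes or a different mix of sorted cells. A value for the whole gene does not show whether a single exon is missing, and the ratio of the OXCT1mKO to the control mean was 0.76. The adjusted p rose to 0.0504 without the filter on low genes, 0.0763 with globin left out of the scaling and 0.0559, 0.225 and 0.162 without control 2, OXCT1mKO 1 and OXCT1mKO 2, respectively.

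**Figure D1:**
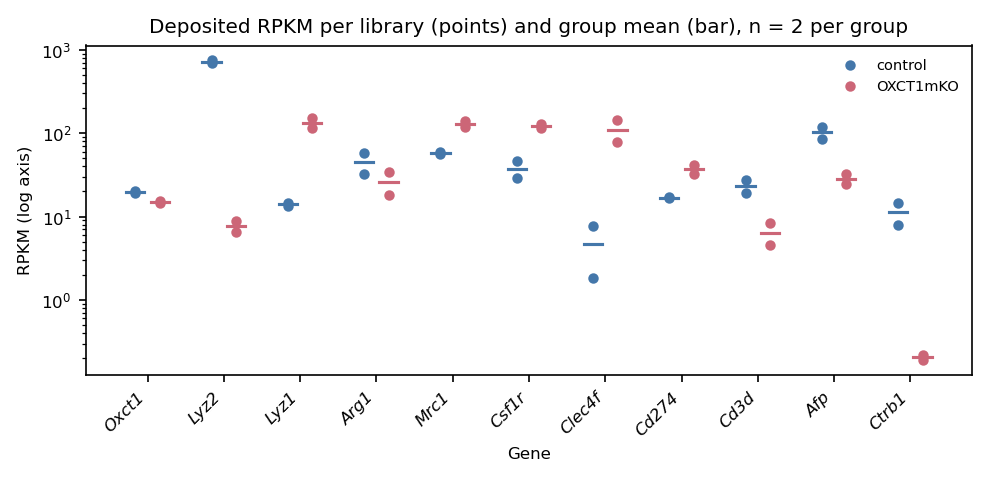
Deposited RPKM on a log axis for 11 genes, with 1 point per library and a bar at the mean of the 2 libraries of each group. Lyz2 fell from 688 and 744 RPKM in the controls to 8.76 and 6.52 RPKM, while Oxct1 moved from 19.3 and 20.3 to 14.7 and 15.4 RPKM.

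The main comparison asked how the sorted samples differed between the 2 groups. The purity of the sorts is not known, and transcripts of other cells were present. Control means were 387 RPKM for the epithelial keratin gene Krt18, 395 for Alb of hepatocytes and 60.0 for the endothelial gene Kdr. The macrophage genes Csf1r and Lyz2 had control means of 37.3 and 716 RPKM. Differences between groups may therefore include those of other cells. With a preset correlation between genes, the list test camera called the markers of Kupffer cells, monocytes and conventional dendritic cells, the interferon genes and class II antigen presentation upward in OXCT1mKO. It called ribosomal proteins, oxidative phosphorylation, the cell cycle and T cell markers downward, the last with 7 of 17 markers lower. With an estimated correlation, where camera has 2 degrees of freedom and little power, it called 0 lists, the lowest adjusted p being 0.487. The largest fold change belonged to Lyz2, the lysozyme of the myeloid lineage, which fell from 716 ± 39.5 to 7.64 ± 1.58 RPKM (SD, n = 2). Its log2 fold change was -6.39 ± 0.15, with a limma adjusted p of 0.00252. The neighbouring gene Lyz1, the lysozyme of Paneth cells, rose from 14.1 ± 0.82 to 133 ± 24.3 RPKM, a log2 fold change of 3.14 ± 0.15. Both genes lie on the minus strand of chromosome 10, Lyz2 from 117277331 to 117282321 and Lyz1 from 117287797 to 117292868. Their sequences are close, so the split of reads between them is uncertain.

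Of the 12523 genes tested with limma, 4110 changed (32.8%), 2058 upward and 2052 downward. With a log2 fold change of at least 1 in size, 532 rose and 200 fell. In 74.7% of tested genes both libraries of one group lay above both of the other, where chance gives 33.3% for a single gene. Genes are not independent, so any difference between libraries that runs along the groups would raise this share. The count of changed genes was 1 without OXCT1mKO 1 and 10 without OXCT1mKO 2, fits in which the lone OXCT1mKO library was taken to vary as the 2 controls do, whereas it was 3461 and 4418 without control 1 and control 2. Scaling each library to the same RPKM sum without globin genes, a choice made after seeing the data, gave a median log2 fold change of 0.10. Under it, 2858 genes were higher and 1421 lower. The main fit applied no such scaling, and the RPKM sums were higher in both controls than in both OXCT1mKO libraries. Globin lay mostly in control 1, so leaving it out brought the sum of that control nearer to those of OXCT1mKO. The shift therefore came from setting the sums equal and not from globin.

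**Figure D2:**
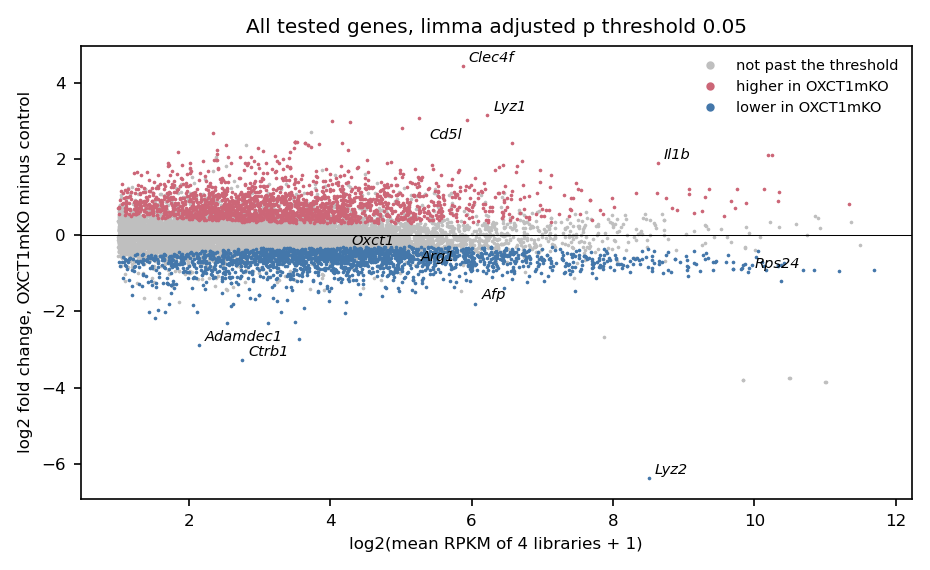
Log2 fold change (OXCT1mKO minus control, log2(RPKM + 1) scale) against log2 mean RPKM of the 4 libraries for the 12523 tested genes, with genes past an adjusted p of 0.05 in colour. Lyz2 stands apart at -6.39, and Clec4f is the highest of the changed genes at 4.43.

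The 10 genes with the largest rise were led by markers of Kupffer cells, the resident macrophages of the liver. Clec4f, a lectin of Kupffer cells, rose from 4.73 ± 4.11 to 110.3 ± 45.2 RPKM, a log2 fold change of 4.43 ± 0.59. Fcna (3.08 ± 0.46), a ficolin, Cd5l (3.01 ± 0.25), a secreted macrophage protein, Folr2 (2.98 ± 0.25), a folate receptor, Vsig4 (2.97 ± 0.28), a complement receptor, and Cd163 (2.67 ± 0.24), the haemoglobin scavenger receptor, rose as well. The rest were Lyz1, Cyp26b1 (2.81 ± 0.55), a retinoic acid hydroxylase, and the chemokine copies Ccl21b (2.44 ± 0.46) and Ccl21c (2.44 ± 0.45). The Ccl21 copies share reads and 3 other rows held the values of Ccl21c, so their levels are uncertain. After Lyz2, the 10 genes with the largest fall included 4 that encode digestive enzymes of the pancreas. These were Ctrb1 (-3.29 ± 0.28), a chymotrypsinogen, Cela2a (-2.32 ± 0.13), an elastase, Amy2a5 (-2.17 ± 0.25), an amylase, and Try4 (-2.03 ± 0.27), a trypsinogen. Adamdec1 (-2.89 ± 0.25), a metalloprotease of tissue macrophages, Car4 (-2.74 ± 0.70, and -1.65 without control 1), a carbonic anhydrase, Serpinb11 (-2.31 ± 0.53), Tff2 (-2.29 ± 0.15), a trefoil peptide of mucus, and Rgs16 (-2.05 ± 0.43), a regulator of G protein signalling, completed the set. All 20 passed the limma threshold, with adjusted p between 0.00252 and 0.0419. With a pseudocount of 0.1 the values were 4.13 for Cd163, -5.16 for Ctrb1, -5.79 for Adamdec1, -5.00 for Amy2a5 and -4.05 for Try4.

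Among the macrophage genes fixed in advance, Mrc1, the mannose receptor used as a marker of alternative activation, rose from 58.0 ± 2.12 to 130.0 ± 14.4 RPKM (log2 fold change 1.15 ± 0.11, limma adjusted p 0.0127). Arg1, which encodes arginase and is used in the same way, was 32.0 and 58.3 RPKM in the controls and 18.1 and 33.9 RPKM in OXCT1mKO. Its log2 fold change of -0.78 ± 0.40 did not pass (limma adjusted p 0.185), and became -1.20 and -0.36 without control 1 and control 2 and -0.34 and -1.21 without OXCT1mKO 1 and OXCT1mKO 2. Cd274, the ligand of PD-1, rose from 16.8 ± 0.27 to 37.0 ± 6.00 RPKM, and the costimulatory gene Cd86 rose from 8.36 ± 1.60 to 20.4 ± 2.57 RPKM. The receptor genes Csf1r (1.71 ± 0.23) and Adgre1 (1.24 ± 0.25) rose. So did the leukocyte gene Ptprc (1.13 ± 0.08), chosen after its values were seen. The rises of Mrc1, Cd274 (1.08 ± 0.13) and Cd86 (1.20 ± 0.16) were of similar size. They therefore cannot be told from a larger share of leukocytes in the OXCT1mKO libraries. Nos2, the inducible nitric oxide synthase, was near 1 RPKM in both groups (0.17 ± 0.27, limma adjusted p 0.633), and was 0.50 without control 1, -0.15 without control 2, 0.01 without OXCT1mKO 1 and 0.34 without OXCT1mKO 2. Alb, the albumin of hepatocytes, was 395 ± 32.6 RPKM in control and 319 ± 58.8 RPKM in OXCT1mKO (limma adjusted p 0.185), with a log2 fold change of -0.32 that became -0.51 and -0.13 without OXCT1mKO 1 and OXCT1mKO 2. S100a8, an abundant neutrophil transcript, was 42.6 and 582 RPKM in the controls and 239 and 154 RPKM in OXCT1mKO, with a log2 fold change of 0.28 ± 1.22 (limma adjusted p 0.873) that became -1.60 without control 1 (limma adjusted p 0.0351), 2.15 without control 2 (0.0194), -0.04 without OXCT1mKO 1 and 0.59 without OXCT1mKO 2.

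Gene lists were compared next, with 43 of the 45 lists large enough to test. With a preset correlation, 24 lists passed the camera threshold, 18 upward and 6 downward. With an estimated correlation, camera called 0 lists, 2 having an unadjusted p under 0.05. For complement the estimated correlation of -0.0641 was below the preset 0.01, yet its unadjusted camera p went from 4.76e-05 to 0.0495. The loss of that call thus came with the 2 degrees of freedom, not with correlation between its genes. Fry called 7 of the 24: complement, alternative activation, oxidative phosphorylation, cytosolic ribosomal proteins, conventional dendritic cell markers, cell cycle, and cholesterol efflux and lipid handling. List members are given below as counts past the limma threshold over all genes, with the count adjusted over the list alone in brackets. The lists share genes, so their calls are not independent. Tested members that are also in another list numbered 9 of 16 for pan-macrophage markers, 9 of 27 for lysosome and phagocytosis, 8 of 20 for alternative activation, 8 of 22 for interferon gamma, 6 of 21 for classical activation, 6 of 14 for complement and 6 of 16 for Kupffer cells. Vsig4, Cd163, Timd4 and Marco, for example, are Kupffer markers that are also in the complement, alternative activation or lysosome lists.

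**Figure D3:**
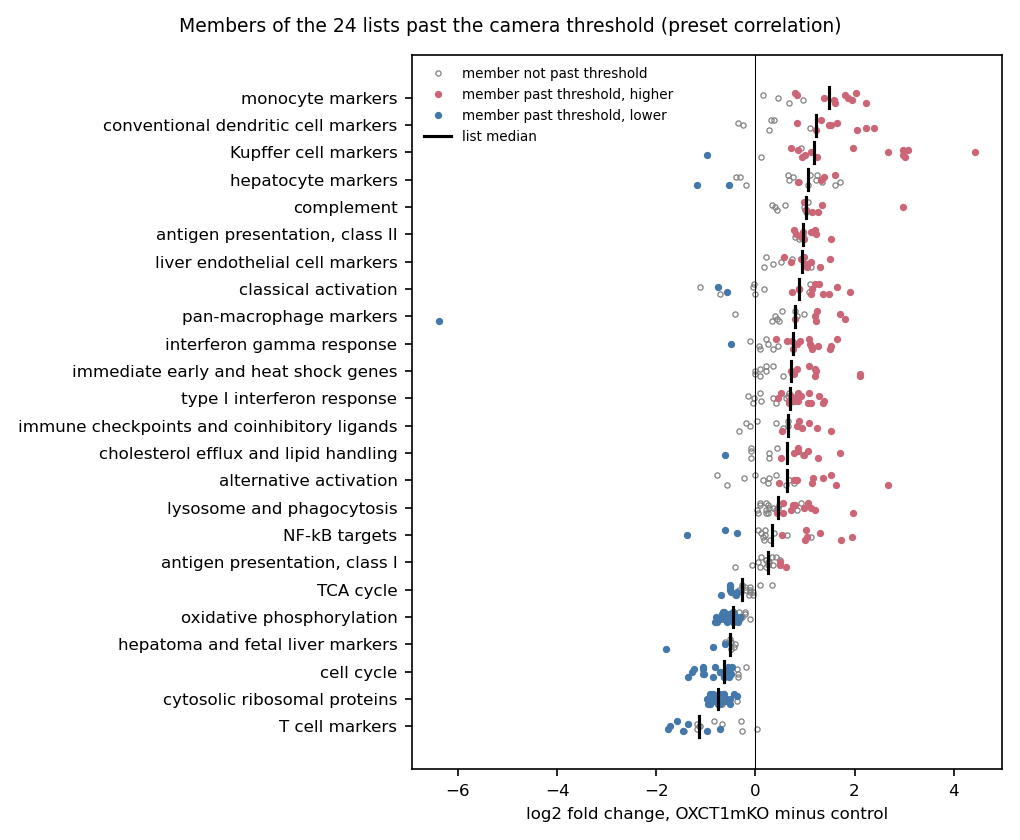
Log2 fold change of each tested member of the 24 lists past the camera threshold, with filled points for members past the limma threshold (red higher, blue lower in OXCT1mKO) and a line at each list's median. List medians run from -1.13 for T cell markers to 1.49 for monocyte markers, and the point at -6.39 among pan-macrophage markers is Lyz2.

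Lists of Kupffer cell, monocyte, conventional dendritic cell and pan-macrophage markers passed camera upward with the preset correlation. Of 16 tested Kupffer cell markers, 13 rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 fold change of 1.18 (camera adjusted p 2.08e-05, adjusted p = 0.539 with an estimated correlation). Timd4, a phosphatidylserine receptor, rose from 1.11 ± 0.24 to 7.37 ± 2.05 RPKM, and the exception was Xlr3a (-0.97). Among 14 monocyte markers, 10 rose (10 adjusted over the list alone), with a median of 1.49 (camera adjusted p 2.08e-05, adjusted p = 0.506 with an estimated correlation). Ccr2, the chemokine receptor of inflammatory monocytes, rose by 2.24 ± 0.17, F13a1 by 1.86 ± 0.21, Treml4 by 1.81 ± 0.22 and Plac8 by 1.58 ± 0.15. Of 15 conventional dendritic cell markers, 9 rose (11 adjusted over the list alone) with a median of 1.23 (camera adjusted p 0.000127, adjusted p = 0.487 with an estimated correlation), or 0.75 with a minimum mean of 5 RPKM. They included the growth factor receptor Flt3 (2.22 ± 0.16), the lectin Clec9a (2.06 ± 0.12) and the chemokine receptor Xcr1 (1.64 ± 0.15, and 3.03 with a pseudocount of 0.1). Of 16 pan-macrophage markers, 6 rose and Lyz2 fell (7 and 1 adjusted over the list alone), the median was 0.81 and Mpeg1 rose by 1.80 ± 0.21. Camera compares list means, and Lyz2 at -6.39 pulled the mean of the pan-macrophage list down to 0.38. No camera result without Lyz2 is given here. That list had a camera adjusted p of 0.0174 (adjusted p = 0.639 with an estimated correlation) and was not called without control 2 (median 0.35, camera adjusted p 0.0996) or with globin left out of the scaling (median 0.92, camera adjusted p 0.054). Lipid-associated macrophage markers did not pass (camera adjusted p 0.879), with Gpnmb and Itgax higher and Cd63 and Cstb lower among 14 (2 and 2 adjusted over the list alone).

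Lists of 4 other cell types passed camera as well. Of 17 T cell markers 7 fell (13 adjusted over the list alone), with a median of -1.13 (camera adjusted p 0.000189, adjusted p = 0.639 with an estimated correlation). The T cell median was -0.74 without control 1 and -0.73 without OXCT1mKO 1, and the call held. The CD3 chain Cd3d fell by 1.73 ± 0.30, the adaptor Lat by 1.76 ± 0.29 and Thy1 by 1.36 ± 0.25. Of 16 liver endothelial markers 10 rose (13 adjusted over the list alone), with a median of 0.95 (camera adjusted p 1.04e-05, adjusted p = 0.601 with an estimated correlation), among them the vascular growth factor receptor Kdr (1.30 ± 0.14) and the phosphatase gene Ptprb, which rose from 33.7 ± 7.95 to 96.3 ± 7.56 RPKM. Of 9 hepatoma and fetal liver markers 3 fell (5 adjusted over the list alone), namely Afp, Gpc3 and Sox9. Afp, the fetal serum protein that hepatoma cells make, fell from 102 ± 22.6 to 28.6 ± 5.80 RPKM. The median was -0.52 (camera adjusted p 0.0065, adjusted p = 0.487 with an estimated correlation), and the call was lost without control 2 (median -0.40, camera adjusted p 0.0601), while the median was -0.85 without control 1. Of 21 hepatocyte markers 4 rose and 2 fell (2 and 1 adjusted over the list alone), with a median of 1.06 (camera adjusted p 0.0441, adjusted p = 0.793 with an estimated correlation). Mup20 (1.33 ± 0.16) and the urea cycle gene Cps1 (1.38 ± 0.36, 0.87 without OXCT1mKO 1 and 2.29 with a pseudocount of 0.1) rose while the fibrinogen gene Fgb fell by 1.17 ± 0.10. The hepatocyte call was lost without control 2 (median 0.83, camera adjusted p 0.246) or OXCT1mKO 1 (median 0.58, camera adjusted p 0.0547). It was also lost, with medians of 1.06 to 1.18, with a minimum mean of 5 RPKM (camera adjusted p 0.0644), without the trend (0.0529), with a variance per group (0.0836) and with globin left out of the scaling (0.136).

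Some cell type lists depended on a single control. The mean log2 level of 16 neutrophil markers was 2.65 in control 1 and 4.43 in control 2, against 3.70 and 3.52 in OXCT1mKO. That list did not pass (camera adjusted p 0.932), but passed downward without control 1 (median -1.04) and upward without control 2 (median 1.14). Its single called member was Retnlg, which fell from 53.1 ± 10.5 to 18.2 ± 5.31 RPKM (1 adjusted over the list alone), and fry gave the list the opposite direction to camera. The 10 tested B cell and plasma cell markers included 0 changed genes by limma, and 0 at an unadjusted p under 0.05. They passed downward without control 1 (median -0.56) and upward without control 2 (median 1.16). The 6 tested erythroid genes included 0 changed genes by limma and 1 at an unadjusted p under 0.05, with a median of -3.78 (camera adjusted p 0.0576), or -0.88 without the filter on low genes. Hba-a1 was 7794 RPKM in control 1, 265 in control 2 and 104 and 94.0 in OXCT1mKO. The erythroid list passed downward when either control was left out (median -1.38 and camera adjusted p 0.00135 without control 1, median -6.17 and camera adjusted p 6.54e-06 without control 2). Natural killer cell markers did not pass (camera adjusted p 0.624), with Klrk1 and Ncr1 higher and Eomes and Gzma lower among 12 (2 and 2 adjusted over the list alone). Camera and fry differed in its direction, and it passed downward without OXCT1mKO 2 (camera adjusted p 0.0474). Plasmacytoid dendritic cell markers (2 of 7 rose, Siglech and Lair1, 1 adjusted over the list alone), mast cell and basophil markers (1 of 6 rose, Gata2, 0 adjusted over the list alone) and stellate cell markers (2 of 12 fell, Acta2 and Tagln, 2 adjusted over the list alone) did not pass either. The mast cell list passed upward without control 2 (camera adjusted p 0.0421). Platelet markers were too few to test as a list, with 3 above the filter, of which Pf4 fell by 0.84 ± 0.15 (1 adjusted over the list alone).

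Lists of interferon genes, antigen presentation and checkpoint genes passed camera upward. Of 28 type I interferon genes 17 rose (20 adjusted over the list alone), with a median of 0.69 (camera adjusted p 5.62e-06, adjusted p = 0.601 with an estimated correlation). Examples were the DNA-sensor family genes Ifi204 (1.36 ± 0.11) and Ifi205 (1.38 ± 0.13), which are close copies, and the antiviral gene Oas3 (1.28 ± 0.19). Of 22 interferon gamma genes 14 rose and Gbp3 (-0.50) fell (14 and 1 adjusted over the list alone), with a median of 0.75 (camera adjusted p 3.05e-05, adjusted p = 0.499 with an estimated correlation). The immunity-related GTPase Iigp1 rose from 14.7 ± 0.68 to 43.5 ± 4.38 RPKM and Irf8 from 32.8 ± 2.82 to 62.4 ± 4.38 RPKM. In class II antigen presentation 10 of 12 genes rose (11 adjusted over the list alone), with a median of 0.97 (camera adjusted p 7.1e-05, adjusted p = 0.539 with an estimated correlation). They included Ciita, the transactivator of class II genes (1.53 ± 0.16), and H2-Eb1, which rose from 520.0 ± 115 to 1199.9 ± 103 RPKM. In class I presentation 3 of 18 genes rose, Tapbp (0.62 ± 0.08), H2-K1 (0.50 ± 0.12, and 0.81 with quantile scaling) and Erap1 (0.49 ± 0.10), or 2 adjusted over the list alone. The class I median was 0.25 (camera adjusted p 0.0161, adjusted p = 0.499 with an estimated correlation), and the call was lost without control 2 (median 0.23, camera adjusted p 0.0773) or OXCT1mKO 2 (median 0.24, camera adjusted p 0.0554), while the median was 0.40 with quantile scaling. Of 15 checkpoint and coinhibitory genes 7 rose (9 adjusted over the list alone), with a median of 0.66 (camera adjusted p 0.00297, adjusted p = 0.487 with an estimated correlation), among them Havcr2, which encodes TIM-3 (1.52 ± 0.12), Tnfrsf14 (1.25 ± 0.12) and Vsir, which encodes VISTA (0.84 ± 0.09). The checkpoint median was 0.36 without control 1. The values do not show which cells the transcripts of these lists came from. In the same libraries the medians of conventional dendritic and Kupffer cell markers were 1.23 and 1.18, and Ptprc, the leukocyte antigen CD45, was 27.7 and 28.0 RPKM in the controls and 62.0 and 62.4 RPKM in OXCT1mKO.

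Lists of classical and of alternative activation passed camera upward, as did NF-kB targets and immediate early genes. Of 21 genes of classical activation 11 rose and 2 fell (11 and 3 adjusted over the list alone), with a median of 0.89 (camera adjusted p 0.0134, adjusted p = 0.564 with an estimated correlation). Il1b rose from 167 ± 35.1 to 624 ± 103 RPKM and Ptgs2, the inducible cyclooxygenase, from 24.3 ± 0.05 to 64.4 ± 11.2 RPKM, while the chemokines Ccl4 (-0.75 ± 0.10, -0.48 after correction for length and GC content and -0.50 with quantile scaling) and Ccl3 (-0.58 ± 0.13) fell. Of 20 genes of alternative activation 9 rose (9 adjusted over the list alone), with a median of 0.64 (camera adjusted p 0.0029, adjusted p = 0.487 with an estimated correlation). Besides Cd163 and Mrc1 they included Il10 (1.16 ± 0.18) and Vegfa (0.78 ± 0.11), a cytokine that restrains inflammation and a vascular growth factor. Of 20 NF-kB targets 7 rose and 3 fell (8 and 3 adjusted over the list alone), with a median of 0.33 (camera adjusted p 0.0187, adjusted p = 0.678 with an estimated correlation). The NF-kB median was 0.52 without control 2. Cd83 rose by 1.94 ± 0.16 and Tnfaip2 by 1.73 ± 0.14, whereas the neutrophil attractant Cxcl1 fell by 1.38 ± 0.15, the monocyte attractant Ccl2 by 0.62 ± 0.10 and Ier3 by 0.36 ± 0.10. Of 18 immediate early and heat shock genes 9 rose (9 adjusted over the list alone), with a median of 0.73 (camera adjusted p 0.000587, adjusted p = 0.601 with an estimated correlation). These transcripts also respond to tissue digestion, and included Egr1 (1.22 ± 0.18), Jun (1.20 ± 0.18) and Nr4a1 (1.20 ± 0.13). For all of these lists the cells of origin are not known. Monocyte, Kupffer and conventional dendritic cell markers had medians of 1.49, 1.18 and 1.23 in the same libraries.

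Lists of complement, of lysosome and phagocytosis, and of cholesterol efflux and lipid handling passed camera upward. Of 14 complement genes 6 rose (6 adjusted over the list alone), with a median of 1.01 (camera adjusted p 0.000171, adjusted p = 0.487 with an estimated correlation), including the properdin gene Cfp (1.27 ± 0.09) and Cfb (1.03 ± 0.09). Of 27 lysosome and phagocytosis genes 11 rose (12 adjusted over the list alone), with a median of 0.46 (camera adjusted p 3.05e-05, adjusted p = 0.487 with an estimated correlation). The efferocytosis receptor Mertk rose by 1.21 ± 0.14 and the inhibitory Fc receptor Fcgr2b, also in the liver endothelial list, by 1.11 ± 0.13. Of 16 genes of cholesterol efflux and lipid handling 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.64 (camera adjusted p 0.00442, adjusted p = 0.487 with an estimated correlation). The median of this list was 0.39 without control 2. The lysosomal lipase Lipa rose by 0.99 ± 0.09, the sterol transporter Npc1 by 1.06 ± 0.12 and the ubiquitin ligase gene Mylip by 1.26 ± 0.11. In contrast, the lipid-binding protein gene Fabp4 fell by 0.62 ± 0.13. Which cells these transcripts came from is not known, and the Kupffer, monocyte and liver endothelial lists had medians of 1.18, 1.49 and 0.95 in the same libraries.

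Lists of ribosomal proteins, oxidative phosphorylation, the TCA cycle and the cell cycle passed camera downward. Of 32 cytosolic ribosomal protein genes 30 fell (32 adjusted over the list alone), with a median of -0.75 (camera adjusted p 2.11e-11, adjusted p = 0.499 with an estimated correlation), or -0.46 with quantile scaling. Rps24 fell from 1278 ± 81.2 to 652 ± 13.3 RPKM and Rpl18 from 789 ± 37.8 to 408 ± 4.63 RPKM. In contrast Malat1, a long noncoding RNA of the nucleus chosen after its values were seen, was 62.4 and 64.7 RPKM in the controls and 121 and 126 RPKM in OXCT1mKO (log2 fold change 0.95 ± 0.09, limma adjusted p 0.0127). Of 32 genes of oxidative phosphorylation 24 fell (28 adjusted over the list alone), with a median of -0.45 (camera adjusted p 1.5e-09, adjusted p = 0.487 with an estimated correlation). Cox6c, a subunit of cytochrome c oxidase, fell by 0.79 ± 0.10 (0.51 with quantile scaling) and Ndufa4 by 0.77 ± 0.09. In the TCA cycle 7 of 22 genes fell (7 adjusted over the list alone), with a median of -0.27 (camera adjusted p 0.00228, adjusted p = 0.539 with an estimated correlation), led by the dehydrogenase Idh2 (-0.70 ± 0.10). The TCA cycle median was -0.15 with globin left out of the scaling, and the call held. Of 26 cell cycle genes 21 fell (24 adjusted over the list alone), with a median of -0.63 (camera adjusted p 1.5e-09, adjusted p = 0.487 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitosis, fell from 76.4 ± 4.40 to 29.3 ± 0.38 RPKM, and Cdc20 and Aurka fell by 1.28 ± 0.12 and 1.04 ± 0.09. The values do not show which cells these transcripts came from, and the T cell and hepatoma lists had medians of -1.13 and -0.52 in the same libraries.

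Fold change also followed gene length. Across 12310 genes, which are not independent replicates, Spearman's correlation of fold change with summed exon length was 0.308, against 0.0959 for the difference between the controls and 0.0511 for that between the OXCT1mKO libraries. The median log2 fold change went from -0.29 in the shortest of 10 equal bins of genes to 0.30 in the longest. The median exon length was 1752 bases for the ribosomal list and 2101 for oxidative phosphorylation, against 4204 for all tested genes. After correction of each library for length and GC content, 3403 genes were past the limma threshold and the 24 lists passed in the same direction, with medians of -0.56 for ribosomal proteins and -0.33 for oxidative phosphorylation. These calls rest on the preset correlation. With an estimated correlation, where camera has 2 degrees of freedom and little power, 0 lists were called after the correction too.

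**Figure D4:**
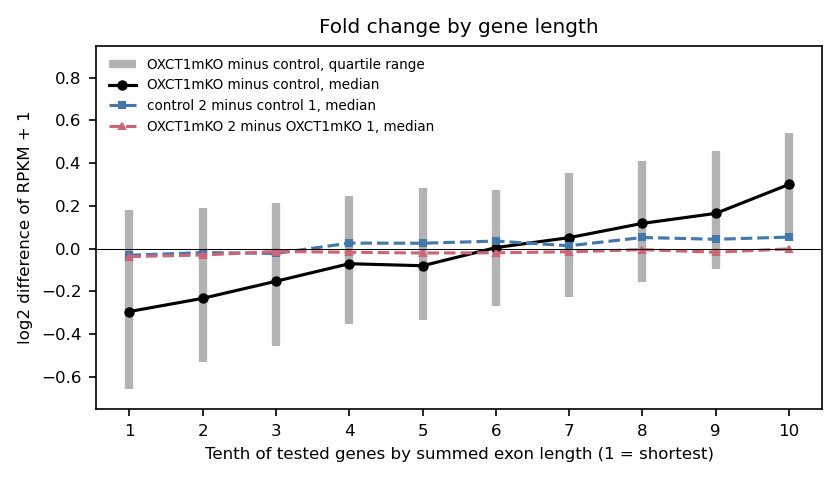
Median log2 difference (RPKM + 1) in 10 equal bins of tested genes ordered by summed exon length, for OXCT1mKO minus control (black, grey bars for the quartile range) and for the differences within each group (dashed). The black line goes from -0.29 to 0.30, while the medians within groups stay between -0.04 and 0.05.

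The remaining process lists did not pass, each having members that moved. In ketone body metabolism 3 of 8 genes rose (3 adjusted over the list alone), among them the monocarboxylate transporters Slc16a3 (0.99 ± 0.12) and Slc16a6 (0.93 ± 0.17), with a camera adjusted p of 0.864. Its median of -0.09 and mean of 0.15 differed in sign, and the median was 0.02 without OXCT1mKO 2 and 0.07 without the filter on low genes. In glycolysis 3 of 19 genes rose, Pfkfb3, Slc16a3 and Pfkp, and 8 fell (4 and 10 adjusted over the list alone), including Tpi1 (-0.80 ± 0.11) and Gapdh (-0.69 ± 0.11, and not called with quantile scaling at -0.41), with a camera adjusted p of 0.19. In fatty acid oxidation 2 of 20 genes rose, Ehhadh and Cpt1a, and 5 fell, Hadh, Etfb, Acads, Eci1 and Acadvl (4 and 7 adjusted over the list alone), with a camera adjusted p of 0.0901 that became 0.0247 without the filter on low genes. Of 24 genes of cholesterol and fatty acid synthesis 4 rose (2 adjusted over the list alone), among them Insig1 and Srebf2, with a camera adjusted p of 0.638. Of 26 chemokine and receptor genes 10 rose and 6 fell (12 and 7 adjusted over the list alone), with a camera adjusted p of 0.375. Of 17 genes of the histone H3K4 methylation machinery Kmt2c, Kmt2e and Setd7 rose and Ash2l, Wdr5 and Dpy30 fell (5 and 4 adjusted over the list alone), with a camera adjusted p of 0.573. The genes that rose lie in the longest bin by exon length. Correction for length and GC content took Kmt2c from 0.83 to 0.50, Kmt2e from 0.94 to 0.70 and Setd7 from 0.59 to 0.36. It took the list median from 0.08 to -0.05.

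In arginine and polyamine metabolism Ass1 and Gatm rose and Srm, Oaz1 and Sms fell among 15 genes (2 and 3 adjusted over the list alone, camera adjusted p 0.638). In the hypoxia response Vegfa and Ndrg1 rose and Ankrd37, Pgk1 and Ldha fell among 20 (2 and 3 adjusted over the list alone, camera adjusted p 0.521). In the unfolded protein response Ern1, Sdf2l1 and Herpud1 rose and Asns, Atf4 and Manf fell among 17 (3 and 3 adjusted over the list alone, camera adjusted p 0.901). In the oxidative stress response Hmox1 rose and Txn1, Me1, Prdx1, Gpx4 and Sod1 fell among 20 (3 and 5 adjusted over the list alone, camera adjusted p 0.879), with a median of 0.04, which was -0.01 without either control, and a mean of -0.05. Of 19 angiogenesis and matrix genes Vegfa and Mmp19 (1.02, and 0.67 without OXCT1mKO 2) rose (1 adjusted over the list alone, camera adjusted p 0.636). The list of mitochondrially encoded transcripts had 0 members in the table and was not analysed here.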

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

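The correction for length and GC content, with either correlation, the variance per group and the scaling without globin genes were chosen after the results were seen, and the other alternatives before the data were examined. The count of changed genes was 4110, and lay between 3403 and 5878 under 13 of the alternatives that kept all libraries. It was 2340 without the filter on low values, where 19514 genes entered the adjustment, 732 with a log2 fold change of at least 1 required and 803 with that minimum and an unadjusted p. Leaving out 1 library gave 1 to 4418 changed genes, with 1 residual degree of freedom in each fit. The low counts came without OXCT1mKO 1 (1 gene) and without OXCT1mKO 2 (10 genes), and these genes were among the 4110. The median SD on the log2 scale was 0.116 between controls and 0.0754 between OXCT1mKO libraries, and the cause was not tested further.

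The Oxct1 log2 fold change stayed negative in each setting, with limma adjusted p between 0.0273 and 0.225. It was past the threshold under 11 of the alternatives that gave it a value. It missed the threshold at -0.37 without the filter, where more genes were tested (limma adjusted p 0.0504), and at -0.26 with globin left out of the scaling (0.0763). That scaling moved the median log2 fold change of all genes from 0.0046 to 0.10, a shift that Oxct1 shared. It also missed the threshold with the replicate block and without control 2, OXCT1mKO 1 or OXCT1mKO 2. Leaving out 1 library gave values from -0.41 to -0.34.

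The number of lists past the threshold lay between 23 and 27 in the camera fits with a preset correlation, leave-outs included. With an estimated correlation, which leaves camera 2 degrees of freedom and little power, it was 0 before and after the correction for length and GC content. Before it, 2 lists had an unadjusted p under 0.05. Fry, which asks another question, called 7. The robust moderation was not run for lists, since camera offers no such setting. Of the lists called, 20 kept their call in each preset-correlation fit. The other 4 were the hepatocyte, pan-macrophage, class I and hepatoma lists, whose adjusted p values stand with their results. The erythroid list passed with the replicate block (camera adjusted p 0.0129), with a variance per group (0.0287), without either control and with globin left out of the scaling (0.0223).

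The replicate numbers are shared between the groups, but the deviations of same-numbered libraries from their group means correlated at only 0.0545, with 2 numbers, so the numbers are not taken as pairs. With the replicate number as a block, 3606 genes were past the threshold, 3311 of them among the 4110, and the Oxct1 value of -0.37 had a limma adjusted p of 0.0577. The block gave 25 lists.

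Of 150 results on named genes, 125 kept their direction and side of the threshold without the filter, 140 of 149 with the length and GC correction and 147 with globin left out of the scaling. Without OXCT1mKO 1 and OXCT1mKO 2, 9 and 16 did. Without 1 library, S100a8 ranged from -1.60 to 2.15 and Nos2 from -0.15 to 0.50, each changing sign, with S100a8 at -0.04 without OXCT1mKO 1. Since counts are not known, the counting error of low genes such as Nos2 cannot be separated from the spread between libraries.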

Other observations

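The list of pancreatic genes, the sex-linked genes, the scaling without globin and both globin tests were chosen only after the results were seen. So were the tests of the TCA cycle and glycolysis against matched random lists, the comparison of macrophage states and both lysozyme tests. The other tests with matched random lists and the test of the Kupffer list without either control were written down before their results were seen.

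Genes of pancreatic acinar cells, which make digestive enzymes, were detected at low levels in the control libraries and were lower in OXCT1mKO. Of 22 such genes, 14 passed the filter on low values and 13 of these fell, with a median log2 fold change of -1.88. The list was prompted by 4 members among the largest falls, Ctrb1, Cela2a, Amy2a5 and Try4, and without them 9 of 10 fell, with a median of -1.54. Both controls lay above both OXCT1mKO libraries in 17 of the other 18. Ctrb1 was 14.5 and 7.95 RPKM in the controls and 0.22 and 0.19 RPKM in OXCT1mKO, and the lipase gene Pnlip was 3.73 and 3.66 against 0.40 and 0.03 RPKM. Members of the trypsinogen and elastase families share sequence, so the split of reads among them is uncertain.

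All 4 libraries are labelled male, and each held Xist as well as transcripts of Y-linked genes. Xist, the RNA of the inactive X chromosome, was 17.2 and 10.4 RPKM in the controls and 16.9 and 20.7 RPKM in OXCT1mKO. The Y-linked gene Kdm5d was 0.68 and 0.60 RPKM in the controls and 1.95 and 2.09 RPKM in OXCT1mKO (log2 fold change 0.88 ± 0.14, limma adjusted p 0.0157), and Eif2s3y was 9.41 and 7.53 against 13.1 and 13.5 RPKM.

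The ribosomal (30 of 32 genes lower) and respiratory chain (24 of 32) lists passed camera downward with the preset correlation (adjusted p = 0.499 and 0.487 with an estimated correlation), and both have median lengths below that of all genes. The ribosomal median of -0.75 lay at percentile 0 of 10000 random lists matched on length, GC content and level. This does not exclude such a bias. Lengths were summed over all annotated exons (6256 bases for Rps24), which can exceed the transcript sequenced. Random genes were drawn singly, although the list's estimated correlation was 0.326. Without control 1, the library with the most globin, the ribosomal median was -0.772. Globin reads there would lower other genes in that control and so raise the fold change, so this value cannot test globin as a reason for a fall. The respiratory median was -0.497 without control 1, which likewise cannot test globin reads as a reason. With all libraries the respiratory median of -0.45 lay at percentile 3.87, above the lower bound of -0.47 of the matched lists. The TCA cycle median of -0.27 lay at percentile 7.53. A shared bias by length, GC content or level may therefore account for the respiratory and TCA cycle falls, although both lists still passed camera after correction for length and GC content alone with the preset correlation (medians -0.33 and -0.26), where 0 lists passed with an estimated one. The glycolysis list, which camera did not call, had a median of -0.34 over 18 members, at percentile 0.74 and below its lower bound of -0.27. Random genes were drawn singly here too, while its estimated correlation was 0.334. The genotype itself and a different mix of sorted cells stay open and were not tested. A larger share of nuclear RNA stays open too, and only Malat1, higher by 0.95, was looked at for it.

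The Kupffer cell, monocyte and conventional dendritic cell lists passed camera upward with the preset correlation, with 13 of 16, 10 of 14 and 9 of 15 markers higher (adjusted p = 0.539, 0.506 and 0.487 with an estimated correlation). A single outlying control is argued against for the Kupffer list, since the Kupffer median was 1.44 and 1.31 without control 1 and control 2. The Kupffer list rose over the lipid-associated list by at least 1.05 in each of the 4 pairs of an OXCT1mKO and a control library, which share libraries. This comparison was chosen after both changes were known. It cannot exclude a larger share of macrophages, because the values do not show how much of the lipid-associated transcripts came from macrophages. A different mix of macrophage states and a change of expression within the same cells stay open and were not tested. A single value per gene and library does not separate them. The same holds for the interferon, class II, checkpoint, activation, NF-kB, complement, lysosome and cholesterol efflux lists. A larger share of macrophages stays open too. Ptprc (1.13), Csf1r (1.71) and Adgre1 (1.24) rose, and the medians of the pan-macrophage, hepatoma and T cell lists were 0.81, -0.52 and -1.13.

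Lyz2 was nearly lost while Lyz1 rose. Reads moved from one gene to the other cannot make up the loss, since the sum of both was 703 and 757 RPKM in the controls and 159 and 122 RPKM in OXCT1mKO, at most 22.6% of a control. Fewer macrophages are argued against by the other pan-macrophage markers, whose median was at least 0.506 with any 1 library left out. An altered Lyz2 locus, as in lines that express Cre recombinase from it, stays open. The labels name no such allele, and genotypes or reads along Lyz2, which would test it, were not used here, while the rise of Lyz1 stays open too.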
